A study of Arabidopsis thaliana with 34 samples.

How the data were processed

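Arabidopsis thaliana material was profiled in 34 samples. Whole seedlings gave 12 mRNA libraries (Col-0, vrn2-5, prt6-1 and vrn2-5 prt6-1, 3 each), 3 VRN2-YFP immunoprecipitations with 3 inputs from vrn2-5 plants that carry VRN2-YFP under the VRN2 promoter, and 3 H3K27me3 immunoprecipitations with 3 inputs from each of Col-0 and vrn2-5. Whole rosettes gave 4 mRNA libraries, 2 of pif4-2 and 2 of vrn2-5 pif4-2. Groups and replicate numbers came from the labels. The labels do not say whether replicates came from separate plantings, so p-values of expression measure the spread between these samples, which may be technical. Age, light and temperature of the plants are not given in the sources used here.

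Per the submitters' processing notes, reads were mapped to TAIR10, with Bowtie and DESeq2 named for RNA, BWA for all immunoprecipitations, MACS2 and MACS3 for VRN2-YFP replicates 1 and 2, and SICER for H3K27me3. No versions or settings were given, and no caller was named for VRN2-YFP replicate 3. Per the labels' protocols, VRN2-YFP was precipitated with the AB290 antibody. The same protocol text stands at the H3K27me3 samples, so the antibody used for the histone mark is not given in the sources used here.

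The seedling table deposited by the authors holds a normalized signal per gene: reads divided by 1 size factor per library. Within each library, low values were whole multiples of a single step, and division by it gave whole reads for 100% of values at a tolerance of 0.01. The design fixed before the data were examined had foreseen a count test for seedlings. Since the unit was normalized, the main test became limma with an intensity-dependent prior on log2(value + 5), fitted to all 12 libraries with genotype as the only term, for 16820 of 18480 genes with a mean of at least 10. The pseudocount and the minimum were chosen after the unit was seen and before any test. Fold changes are on this log2(value + 5) scale, which understates changes of low genes. A quasi-likelihood test of edgeR on the recovered reads was added as an alternative.

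The rosette table deposited by the authors holds raw read counts per gene, which were tested with edgeR's quasi-likelihood method (TMM scaling) on the 4 libraries alone, for 18561 of 21884 genes. Standard errors of rosette log2 fold changes were derived from the F statistic. The same table gives the authors' log2 fold change and p-values for this comparison, which are named as the authors' deposited table wherever printed. Gene starts, ends and lengths, of the kind other than a measurement, also came from this deposited table, in TAIR10 coordinates counted from 1. No coordinates were found there for 650 seedling genes, MRD1, ICL and AT4G39675 among them. The gene set is not the full annotation: it held 1 of the 12 seed maturation genes and 24 of the 28 developmental Polycomb targets fixed below. All nuclear genes, where named below, means the 21713 with coordinates there. Symbols came from the fixed lists, this table or the RefSeq names of assembly TAIR10.1, which covered 18476 seedling genes.

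VRN2-YFP peaks were called by the authors in each replicate separately. Column 7 holds the fold over background at the peak and column 9 the -log10 of the q-value, as the authors' peak caller wrote them. A peak counted as reproducible when merged intervals held a peak from at least 2 of the 3 lists, with an overlap of at least 1 bp. H3K27me3 tables, 1 per replicate, hold counts of reads in each region for libraries A and B, the ratio A over B of the authors' normalized reads, and p-values adjusted as a false discovery rate in each direction, per the file headers. The headers do not name A and B. They were read as vrn2-5 and Col-0 from the order in the name of the comparison, and every direction of H3K27me3 given here rests on that reading. A region was reproducible when overlapping regions passed 0.05 in the same direction in at least 2 tables. Genes were bound, marked, lower or higher when a peak or region overlapped the gene body or 1 kb upstream, and overlaps were tested with Fisher's exact test, two-sided. Peak positions were also compared with 1000 random circular shifts of the peaks along the 5 chromosomes.

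Before the data were examined, 18 gene lists were fixed: PIF and shade induced, light receptors and PIFs, early auxin response, gibberellin and brassinosteroid, cell wall loosening, hypoxia response, N-degron pathway, Polycomb machinery, developmental Polycomb targets, photosynthesis, anthocyanin and flavonoid, circadian clock, salicylate defence, abscisic acid and cold, heat shock, seed maturation, root tissue markers and senescence markers. The last 3 stand for tissues or stages that the samples could also hold. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over 17 lists within a comparison and 119 tests in all. Other p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05.

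Genes named in the text followed a rule fixed before the data were examined. It took VRN2, PRT6 and PIF4, then for each of 4 comparisons the 6 largest changes in each direction among genes past the threshold whose replicates did not overlap, up to 3 members past the threshold from each list, and the 6 members of the PIF and shade list with the smallest p. For chromatin it took genes with a peak, an H3K27me3 difference and an expression change (0 genes), up to 3 bound members of each list, and the 5 peaks of highest mean fold. Genes outside the rule are said to be chosen after their values were seen. Near-identical copies, such as the SAUR cluster on chromosome 5 and the LHCB1 genes, can share reads, and the strand setting of the counting is not given in the sources used here, so values of copies and of overlapping genes are uncertain.

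Seedling libraries held 1.21 to 27.9 M recovered reads and fell into 6 deep (at least 5 M) and 6 shallow libraries, with both kinds in every genotype. Rosette libraries held 15.9 to 26.3 M reads. On simulated data with 200 changed genes, the seedling test recovered 7.5% of 2-fold and 63% of 4-fold changes for vrn2-5 against Col-0, with 3 false calls among 16592 genes. The rosette test recovered 0% of 2-fold and 7% of 4-fold changes among 17864 genes, with 3.5 false calls on average. Limma on the H3K27me3 folds, an added alternative, recovered 97.5% of simulated regions with a log2 change of -1 among 3786 regions, with 4 false calls. In the data 1 region was reproducible at a fold of at least 2, so recovery of the smaller differences seen there is not known.

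Alternatives were other scaling, no filter, DESeq2, a replicate block, each replicate left out in turn, only the libraries compared, stricter peak and region thresholds, other overlap rules, and several added after the data were seen, among them a term for replicate 3, whose libraries stood apart in every genotype. 4 columns of per-sample values that matched no sample of the series were not used. The 650 genes without coordinates, and organellar genes, stayed out of the overlaps with chromatin. Input libraries entered only through the authors' peak calling. An immunoprecipitation from plants without the tagged protein was not analysed here.

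Calculations used R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.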

Results

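Seedlings and rosettes of Arabidopsis were compared to learn how VRN2, a subunit of the Polycomb repressive complex 2 that deposits the repressive histone mark H3K27me3, bears on the repression by light of growth genes that PIF transcription factors activate. The mutants vrn2-5 and pif4-2 affect VRN2 and the growth-promoting factor PIF4. The mutant prt6-1 affects PRT6, the ubiquitin ligase of the N-degron pathway that marks VRN2 and other proteins for breakdown. Seedling mRNA came from 4 genotypes with 3 libraries each, and rosette mRNA from 2 genotypes with 2 libraries each. Seedling levels are the authors' normalized reads per gene. A single read was worth 0.205 to 5 normalized reads, so low genes were measured coarsely in the 6 shallow libraries. In all 4 genotypes replicate 3 stood apart from replicates 1 and 2: anthocyanin and flavonoid genes averaged -1.21 to -0.988 relative to the Col-0 mean in replicate 3 and 0.254 to 0.788 in the others, and abscisic acid and cold genes 0.535 to 1.19 against -0.42 to -0.133.

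VRN2 (AT4G16845, chromosome 4, 9476069 to 9479878) was lower in every library labelled vrn2-5. Its normalized reads were 116, 163 and 135 in Col-0 and 50.1, 45 and 50.3 in vrn2-5, and 118, 135 and 130 in prt6-1 against 62.9, 36.7 and 76.8 in vrn2-5 prt6-1. The log2 differences were -1.41 (SE 0.242, n = 3 against 3; adjusted p = 0.293 by limma) and -1.11 (SE 0.242; adjusted p = 1), and the first passed with DESeq2 (adjusted p = 0.00403). In rosettes VRN2 stood at 18.6 and 18.3 CPM in pif4-2 and at 6.98 and 5.62 in vrn2-5 pif4-2. PRT6 (AT5G02310, chromosome 5, 473868 to 482942) was not lower in the libraries labelled prt6-1. It read 0, 46 and 57.7 in Col-0, 10.7, 0 and 43.6 in vrn2-5, 49.6, 142 and 93.8 in prt6-1, and 122, 59.6 and 94.4 in the double mutant, so the label prt6-1 is not checked by this gene and is used below as the labels give it. PIF4 (AT2G43010, chromosome 2, 17886101 to 17889087) averaged 501.6 normalized reads in Col-0 (SD 104), 363.1 in vrn2-5 (SD 195), 338.0 in libraries labelled prt6-1 (SD 97.4) and 355.8 in the double mutant (SD 42.1, n = 3 each). PIF4 transcript was also present in rosettes, at 64.4 and 52.3 CPM in libraries labelled pif4-2 and 60.3 and 20.5 in those labelled vrn2-5 pif4-2. Both rosette genotypes carry the pif4-2 label, so this gene does not check it and the label is used as given.

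In seedlings, 4 genes differed between vrn2-5 and Col-0. MRD1 (AT1G53480, not in the table with coordinates) fell from 219.5 normalized reads (SD 28.7) to 0.178 (SD 0.307, n = 3 each), and the aspartyl protease family gene AT1G03220 (chromosome 1, 786832 to 788722) fell from 1060 (SD 210) to 305.1 (SD 32.6). QQS (AT3G30720, chromosome 3, 12349047 to 12349933), an orphan gene that affects leaf starch, rose from 15.1 (SD 15.2) to 333.6 (SD 67.9). AT3G29633 (chromosome 3, 11452509 to 11453528) had no read in Col-0 and 62.2 normalized reads in vrn2-5 (SD 26.2), at least 83.1-fold higher against a floor of 3 reads over the Col-0 group. The log2 differences were -5.43 (SE 0.418; adjusted p = 0.000988) for MRD1, -1.77 (SE 0.185; adjusted p = 0.00833) for AT1G03220, 3.66 (SE 0.389; adjusted p = 0.00833) for AT3G29633 and 4.45 (SE 0.546; adjusted p = 0.0249) for QQS. MRD1 rested on 2 reads in vrn2-5 against 981 in Col-0, a ratio of 521 with a 95% counting interval of 144 to 4300.

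Limma called 2 genes higher and 2 lower among 16820, with 480 at an unadjusted p under 0.05, while DESeq2 called 6 higher and 5 lower (11). Each of the 4 genes had the same sign within the deep libraries, with 1 library against 1, and within the shallow, with 2 against 2. They were called from these same libraries, so this agreement was largely fixed in advance and does not test an effect of depth. The groups did not overlap for 5.5% of genes, where chance gives 10%. The number of calls moved with single libraries: it was 23 (19 higher and 4 lower) without Col-0 replicate 3, 17 (2 higher and 15 lower) without vrn2-5 replicate 1, 2 without vrn2-5 replicate 2 and 1 without Col-0 replicate 1. Without Col-0 replicate 1 or vrn2-5 replicate 2, AT1G03220 and AT3G29633 missed the threshold (adjusted p = 0.0594 and 0.0553 for both), as did QQS (adjusted p = 0.106 and 0.173, and 0.188 without vrn2-5 replicate 3). At pseudocount 1 limma called 1 gene higher and 3 lower, of which 3 were among the 4 above. QQS lost its call there (adjusted p = 0.42 by limma).

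Of the 2 genes higher in vrn2-5, both were also called higher in libraries labelled prt6-1, and of the 2 lower genes MRD1 was. AT3G29633 averaged 81.7 normalized reads there (SD 19.3) and QQS 254.8 (SD 55.1), while MRD1 averaged 1.16 (SD 1.01, n = 3 each). Independent lists of these sizes would share 0.00333 higher and 0.000357 lower genes. In 20 simulations of unchanged groups with a simulated Col-0 group in common, 0.05 genes were shared on average. With nothing changed few calls can arise, and the simulated genes were independent. The simulations therefore cannot show what the structure of the real Col-0 libraries adds. Part of the excess may come from the shared Col-0 libraries, which are too few to divide.

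Genes induced by PIF factors and shade leaned upward as a group in seedlings labelled vrn2-5, a call that held only at the preset correlation of camera. In vrn2-5 against Col-0, 26 of 28 measured members were positive, with a median log2 difference of 0.42 (adjusted p = 5.7e-06, and adjusted p = 0.826 with an estimated correlation). The largest shifts relative to error were in CKX5, a cytokinin oxidase (39.6 normalized reads, SD 12.2, to 87.0, SD 24.3), and SAUR23, a gene of the auxin-induced SAUR family linked to cell expansion (42.1, SD 16.1, to 74.5, SD 10.6). In vrn2-5 prt6-1 against prt6-1, 27 of 28 members were positive with a median of 0.775 (adjusted p = 1.89e-17, and adjusted p = 0.0651 with an estimated correlation). CKX5 went from 54.2 (SD 18) to 118.8 (SD 25.6), SAUR19 from 46.0 (SD 7.73) to 106.3 (SD 34.5) and SAUR21 (AT5G18030) from 77.4 (SD 30.8) to 239.7 (SD 116, n = 3 each). No single member passed in either comparison, over all genes or adjusted over the list alone.

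The list means of single libraries overlapped between vrn2-5 and Col-0, with 0.295 in Col-0 replicate 1 and 0.246 in vrn2-5 replicate 3. They did not overlap in the other comparison, at 0.995, 0.911 and 0.566 in vrn2-5 prt6-1 against -0.351, 0.107 and 0.426 in prt6-1. Within depth, the list mean was higher by 0.446 in 2 shallow libraries of vrn2-5 against 2 of Col-0, and by 0.514 in 2 deep libraries of vrn2-5 prt6-1 against 2 of prt6-1. The other values within depth set 1 library against 1, with no replicate check (0.342 in deep and 1.26 in shallow libraries). An exact permutation of libraries within each PRT6 background gave a mean difference of 0.587 and p = 0.01 over 400 relabellings, two-sided, or 0.17 adjusted over 17 lists. With 1 replicate 3 library kept on each side, the exact p was 0.0139 over 144 relabellings, or 0.236 adjusted. This is the smallest p that 144 relabellings can give two-sided, so a list alone at it cannot pass after adjustment over 17 lists. The same holds for a list alone at the smallest p of 400 relabellings. With replicate 3 as a term, camera gave adjusted p = 8.26e-08 and 9.91e-21, and adjusted p = 0.845 and 0.24 with an estimated correlation. In libraries labelled prt6-1 against Col-0, 16 of 28 members were positive (median 0.0683, adjusted p = 0.853). Other members named by the rule in vrn2-5 against Col-0 were PAR1 at 0.46 (SE 0.197), SAUR20 at 0.90 (SE 0.39), HAT2 at 0.65 (SE 0.331) and ATHB2 at 0.65 (SE 0.336). SAUR23, SAUR20 and SAUR22 stood at 0.98 (SE 0.308), 1.16 (SE 0.39) and 1.07 (SE 0.361) in vrn2-5 prt6-1 against prt6-1.

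**Figure D1:**
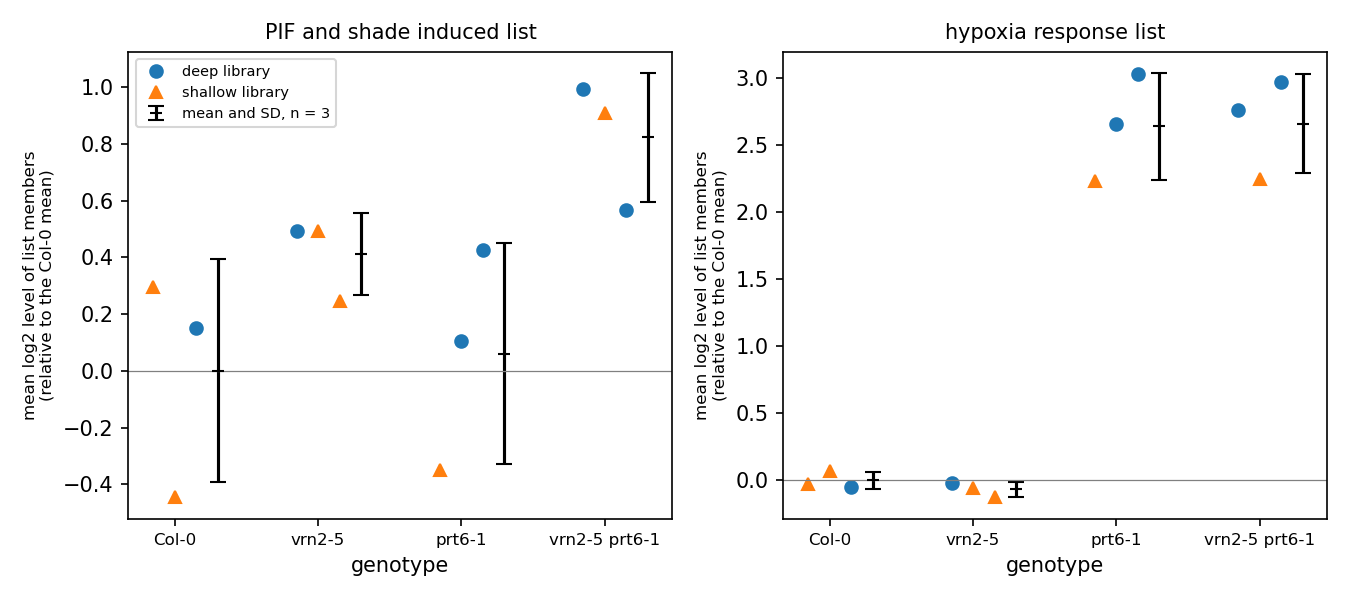
Mean log2 level of the members of the PIF and shade induced list (28 genes) and the hypoxia response list (33 genes) in each seedling library, relative to the Col-0 mean, by genotype. Circles are deep and triangles shallow libraries, and the bar gives mean and SD of 3. The PIF list averages 0.412 in vrn2-5 (SD 0.143) and 0.824 in vrn2-5 prt6-1 (SD 0.227), and the hypoxia list 2.64 in prt6-1 (SD 0.401).

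In libraries labelled prt6-1, genes of the low-oxygen response rose strongly. Of 33 measured members of the hypoxia list, 18 rose over all genes tested and 23 adjusted over the list alone, with a median log2 difference of 2.63. PCO1 (chromosome 5, 4898641 to 4900734) and PCO2 (chromosome 5, 15974270 to 15976270), the cysteine oxidases that feed proteins into the N-degron pathway, rose from 21.5 (SD 9.08) to 959.2 (SD 134) and from 12.4 (SD 2.54) to 636.7 (SD 250). PGB1 (chromosome 2, 6982531 to 6983777), a phytoglobin that scavenges nitric oxide, went from 51.6 (SD 9.64) to 1972 (SD 753), and ICL, the isocitrate lyase of the glyoxylate cycle, from 39.1 (SD 21.4) to 3842 (SD 551). AT5G05200 (chromosome 5, 1544007 to 1547207) fell from 783.7 (SD 48.6) to 128.3 (SD 5.04, n = 3 each).

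The log2 differences were 5.23 (SE 0.236; adjusted p = 1.84e-06) for PCO1, 5.14 (SE 0.348) for PCO2, 5.07 (SE 0.37) for PGB1, 6.54 (SE 0.397; adjusted p = 2.53e-05) for ICL, 6.16 (SE 0.513) for the acyl desaturase SAD6, 5.34 (SE 0.387) for AT3G03270 and 4.99 (SE 0.364) for AT4G39675. HRE2, an ethylene response factor of the N-degron substrates, rose by 2.39 (SE 0.377; adjusted p = 0.0343), from 3 reads to 170, a ratio of 33.5 with a counting interval of 11.5 to 162. AT5G24240 fell by 3.19 (SE 0.495; adjusted p = 0.0302) and AT5G05200 fell by 2.56 (SE 0.114; adjusted p = 1.84e-06). The calls of HRE2 and AT5G24240 were lost on leaving out any of the 6 libraries, with adjusted p = 0.0667 to 0.286 and 0.0568 to 0.197, and edgeR did not call AT5G24240 (adjusted p = 0.136).

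In all, 28 genes rose and 3 fell (31, with 696 at an unadjusted p under 0.05), and DESeq2 called 55 (47 higher and 8 lower). Without Col-0 replicate 3 the number was 51. The groups did not overlap for 9.55% of genes, where chance gives 10%. All 31 genes kept their sign within the deep libraries, where Col-0 had 1, as did the 29 tested within the shallow ones, where prt6-1 had 1. Since the genes were called from these same libraries, this too was largely fixed in advance. Camera on the hypoxia list gave adjusted p = 2.89e-72, and adjusted p = 0.00105 with an estimated correlation. The senescence markers were lower as a set, with 0 of 4 positive, a median of -0.59 and adjusted p = 0.00918 (adjusted p = 0.0901 with an estimated correlation), though no member passed, over all genes or adjusted over the list alone. Among them ORE1 stood at -0.73 (SE 0.3) and NAP at -0.56 (SE 0.255).

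The prt6-1 label carried much the same genes in the vrn2-5 background. In vrn2-5 prt6-1 against vrn2-5, 33 genes rose and 2 fell, and 25 of the higher and 1 of the lower genes were also called in prt6-1 against Col-0, where independent lists would share 0.0549 and 0.000357. These comparisons share no library. Of the hypoxia list, 18 of 33 members rose (25 adjusted over the list alone, median 3.03), with adjusted p = 1.03e-61 and adjusted p = 0.00185 with an estimated correlation. PTR1, a dipeptide transporter, also differed by 4.43 (SE 0.534; adjusted p = 0.00368), from 0 reads in vrn2-5 to 112.3 normalized reads in the double mutant (SD 57.3). PTR1 averaged 61.9 in Col-0 (SD 11.4), at least 87.8-fold above the same floor in vrn2-5 (adjusted p = 0.0703), and is named here after its values were seen.

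Of 16820 genes, 1039 had an unadjusted p under 0.05 in vrn2-5 prt6-1 against vrn2-5, and DESeq2 called 63. Of these 54 were higher and 9 lower, and with replicate 3 as a term 43 were higher and 11 lower. Groups did not overlap for 11% of genes, where chance gives 10%. The double mutant against Col-0 had 31 genes higher and 4 lower, with 18 of 33 hypoxia members higher (25 adjusted over the list alone; adjusted p = 2.23e-62, and adjusted p = 0.00178 with an estimated correlation). DESeq2 called 52 genes higher and 16 lower in that comparison, and with replicate 3 as a term 40 were higher and 17 lower. It had 53 calls without Col-0 replicate 3, 23 without vrn2-5 prt6-1 replicate 1 and 23 with only the 6 libraries compared. The PIF and shade list leaned the same way there, with 25 of 28 positive and a median of 0.871 (adjusted p = 3.94e-11, and adjusted p = 0.0771 with an estimated correlation). None of its members passed over all genes and 5 did adjusted over the list alone: CKX5 at 1.49 (SE 0.307), SAUR23 at 1.46 (SE 0.308), SAUR20 at 1.304 (SE 0.39), SAUR19 at 1.04 (SE 0.315) and HAT2 at 1.08 (SE 0.331).

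In vrn2-5 prt6-1 against prt6-1, no single gene passed. MRD1, QQS and AT3G29633 were already near their vrn2-5 level in prt6-1, so only AT1G03220, at 1408 normalized reads in prt6-1 (SD 195) and 1316 in the double mutant (SD 252), had room for a like change. MRD1 differed by 0.75 (SE 0.418), AT1G03220 by -0.11 (SE 0.185), AT3G29633 by -0.37 (SE 0.389) and QQS by 0.19 (SE 0.546, n = 3 against 3). Early auxin response genes were higher as a set, with 16 of 18 positive, a median of 0.248 and adjusted p = 2.52e-05 (adjusted p = 0.166 with an estimated correlation). Of these the auxin repressor genes IAA19 and IAA2 stood at 1.45 (SE 0.51) and 0.66 (SE 0.263). Library means of the auxin list overlapped, at 0.829, 0.636 and 0.444 in vrn2-5 prt6-1 against -0.193, 0.0953 and 0.609 in prt6-1. For this list the exact permutation of libraries over both backgrounds gave p = 0.125, or 0.659 adjusted. The Polycomb machinery list, which holds the mutated gene VRN2, was lower as a set by camera, with 5 of 15 positive and a median of -0.19 (adjusted p = 0.00252, and adjusted p = 0.166 with an estimated correlation). VRN2 was its only member past the threshold adjusted over the list alone. Library means overlapped, at 0.332, -0.413 and 0.256 in vrn2-5 prt6-1 against 0.114, 0.516 and 0.378 in prt6-1. The exact permutation of libraries over both backgrounds gave p = 0.28 for this list, or 0.952 adjusted.

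Limma called 0 genes, edgeR 0 and DESeq2 0, with 191 genes at an unadjusted p under 0.05, of which 122 were higher. A difference between the vrn2-5 effects with and without the prt6-1 label passed for MRD1 alone, with an interaction of 6.18 on the log2 scale (SE 0.591; adjusted p = 0.00895). For this interaction 225 genes had an unadjusted p under 0.05, edgeR called 0 and DESeq2 6. The number was 0 without Col-0 replicate 1, 2 without Col-0 replicate 2, 4 without Col-0 replicate 3, 5 without vrn2-5 replicate 1 and 2 without vrn2-5 replicate 3. Across genes, which are not independent replicates, the vrn2-5 effects in both backgrounds had a Pearson correlation of 0.0597 and a Spearman correlation of 0.117, against 0.406 and 0.357 for the prt6-1 effects. No list passed in the interaction, where the PIF and shade list had 22 of 28 positive and adjusted p = 0.394.

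Other lists passed camera at the preset correlation in vrn2-5 prt6-1 against vrn2-5: PIF and shade (23 of 28 positive, adjusted p = 0.0187), early auxin response (16 of 18, adjusted p = 0.0238) and the N-degron list (8 of 9, adjusted p = 0.0187, with 1 member higher over all genes and 1 adjusted over the list alone). All of these had adjusted p = 0.487 with an estimated correlation. Senescence markers were lower there (0 of 4 positive, adjusted p = 0.0096, and adjusted p = 0.0918 with an estimated correlation). In the double mutant against Col-0, early auxin response genes were higher (17 of 18, adjusted p = 0.000135, and adjusted p = 0.203 with an estimated correlation) and senescence markers lower (0 of 4, adjusted p = 0.00531, and adjusted p = 0.0771 with an estimated correlation). For vrn2-5 against Col-0, camera did not pass for light receptors and PIFs (6 of 15 positive, adjusted p = 0.68), gibberellin and brassinosteroid (14 of 23, 0.852), cell wall loosening (13 of 19, 0.513) or developmental Polycomb targets (4 of 9, 0.852). It did not pass for photosynthesis (8 of 18, 0.852), anthocyanin and flavonoid (3 of 5, 0.852), circadian clock (6 of 15, 0.703) or salicylate defence (4 of 7, 0.92). Abscisic acid and cold (6 of 11, 0.68), heat shock (3 of 4, 0.629) and root tissue markers (2 of 7, 0.394) did not pass either, and no member of the 12 seed maturation genes was in the seedling table.

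In rosettes labelled vrn2-5 pif4-2, both libraries had more QQS and AT3G29633 and less PTR1 and AT1G03220 than both labelled pif4-2, though edgeR called none of them. With a replicate block edgeR called 3 genes, of which 2 were also called in vrn2-5 seedlings. QQS read 0.939 and 1.8 CPM in pif4-2 against 33.8 and 58.9 in vrn2-5 pif4-2, and AT3G29633 0.268 and 0.0408 against 15.1 and 11.1. PTR1 read 68.8 and 67.3 against 6.41 and 1.71, and AT1G03220 52.9 and 47.4 against 17.3 and 14.4. The log2 fold changes were 5.13 (SE 0.599) for QQS, 6.39 (SE 0.807) for AT3G29633 and -1.65 (SE 0.243) for AT1G03220, each with adjusted p = 0.945 and n = 2 against 2. These 4 genes were chosen after their values were seen, and 3 are those called in vrn2-5 seedlings, with the same sign in 3 of 3. The PIF and shade list gave no call (13 of 26 positive, median -0.056, upward by camera with adjusted p = 0.769), though its library means were -0.606 and -0.31 in vrn2-5 pif4-2 against 0.0252 and -0.0252 in pif4-2, so a change is left open. By the rule SAUR21 (AT5G18030) stood at 1.55 (SE 0.496), PRE1 at 0.87 (SE 0.311), PAR2 at 1.48 (SE 0.601), PAR1 at -3.64 (SE 1.83), SAUR20 at 0.96 (SE 0.556) and PRE6 at 0.58 (SE 0.345), all with adjusted p = 0.945. On leaving out each rosette library in turn, which sets a lone library against 2, SAUR21 ranged from 0.741 to 2.045 and PRE1 from 0.568 to 1.096. PAR2 ranged from 0.552 to 2.023, PAR1 from -8.892 to -2.615, SAUR20 from 0.0779 to 1.491 and PRE6 from 0.247 to 0.994.

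Among 18561 genes edgeR called 0, with 441 at an unadjusted p under 0.05, while DESeq2 called 7. The authors' deposited table lists 7 genes at an adjusted p under 0.05, of which 5 are higher (QQS, AT3G29633, AT4G23680, SAG29 and DIN2) and 2 lower (PTR1 and AT1G03220). Replicates differed widely: 11464 genes passed without vrn2-5 pif4-2 replicate 1, 1825 without vrn2-5 pif4-2 replicate 2, and 2 without either pif4-2 replicate, each test with a lone library assumed to vary like the other group. In vrn2-5 pif4-2 replicate 2, the log2 ratio to the pif4-2 mean fell with gene length (Spearman -0.406 across genes, which are not independent), with medians of 0.536 in the shortest and -0.661 in the longest of 4 length groups. Senescence markers were higher as a set (4 of 5 positive, 1 adjusted over the list alone; adjusted p = 0.0152, and adjusted p = 0.77 with an estimated correlation), with SAG29 at 5.29 (SE 1.14) and SAG13 at 5.80 (SE 2.05), while SGR1 stood at 0.34 (SE 0.273), ORE1 at 0.30 (SE 0.858) and NAP at -0.23 (SE 0.728). SAG29 read 22.5 CPM in replicate 1 and 2.74 in replicate 2, against 0.268 and 0.327 in pif4-2. SAG13 read 79.8 CPM in replicate 1 and 0.76 in replicate 2, against 0.67 and 0.653 in pif4-2. The senescence list mean was 2.75 in replicate 1 and 0.654 in replicate 2, against 0.328 and -0.328 in pif4-2. Replicate 1 thus carried most of this call. The N-degron list was lower by camera, with 1 of 8 positive (adjusted p = 0.0164, and adjusted p = 0.77 with an estimated correlation). VRN2, the gene mutated here, was its only member lower adjusted over the list alone, and the list was not tested without it. List means were -0.203 in replicate 1 and -0.756 in replicate 2, the library whose ratios fell with gene length. Across 15811 genes the rosette and the seedling vrn2-5 changes had a Pearson correlation of 0.0325 and a Spearman correlation of 0.0659. Tissue and table differ, so the difference between them was not tested.

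**Figure D2:**
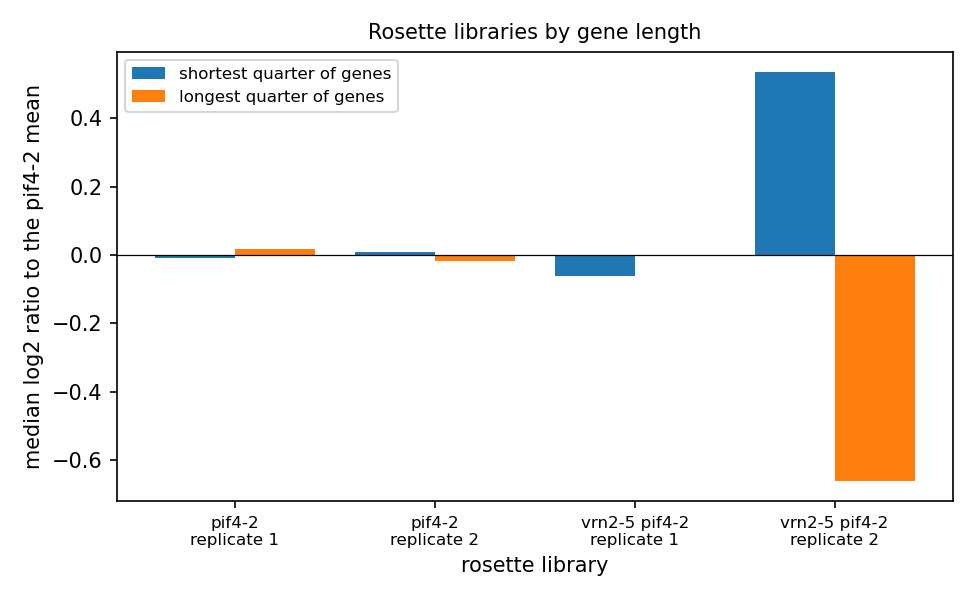
Median log2 ratio to the pif4-2 mean of the shortest and the longest of 4 groups of genes by annotated length, for each of the 4 rosette libraries. In vrn2-5 pif4-2 replicate 2 the shortest group sits at 0.536 and the longest at -0.661, and in the other libraries both lie between -0.0602 and 0.0169.

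VRN2-YFP peaks lay over genes of the photosynthesis list more often than over other genes in seedlings. Of 18 photosynthesis genes, 9 carried a reproducible peak (odds ratio 24.3, adjusted p = 1.49e-07 by Fisher's exact test), the highest over LHCB4.1 (peak at chromosome 5, 210300 to 210849; mean fold over background 5.6, SD 3.28, n = 3), LHCB1.1 (chromosome 1, 10474711 to 10476116; 2.85, SD 0.724) and LHCB1.3 (chromosome 1, 10478046 to 10479223; 2.3, SD 0.314), all chlorophyll-binding antenna proteins. RBCS1A, a small subunit of Rubisco, was among the 9 with a mean fold of 1.99 (SD 0.0987) in 2 of the 3 lists. Of the 18 photosynthesis genes, 4 were marked with H3K27me3 (adjusted p = 0.645 by Fisher's exact test). LHCB4.1, LHCB1.1 and LHCB1.3 had no H3K27me3 region, while RBCS1A had one. Of the 20 highest genes in Col-0, 8 were bound, so high transcription stays open as a source of these peaks. Peaks at the other lists did not pass. The auxin genes IAA30, GH3.2 and GH3.3 (4 of 21 bound, adjusted p = 0.0749) and the meristem and flower regulators KNAT1, PI and LFY (4 of 24 developmental targets, adjusted p = 0.0805) had peaks of mean fold 2.5, 2.31, 2.11, 2.41, 2.25 and 2.18. Of the PIF and shade list 3 of 30 were bound (adjusted p = 0.332), all in the gene body: the sulfotransferase gene ST2A (chromosome 5, 2175127 to 2176140; 2.22, SD 0.34), CKX5 (chromosome 1, 28317475 to 28318040; 2.04, SD 0.111) and the auxin synthesis gene YUC9 (chromosome 1, 1104622 to 1105501; 1.82, SD 0.185), each in 2 of the 3 lists. No gene of the hypoxia list was bound (0 of 29, adjusted p = 0.824).

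The other bound list members by the rule were GA3OX2 (3.02) and GA20OX2 (1.94) of gibberellin synthesis, the cell wall enzyme gene XTH22 (2.67), the flavonoid regulator TT8 (2.18), FMO1 (2.7) and PR1 (2.64) of salicylate defence, RAB18 (3.09) and CBF3 (2.25) of abscisic acid and cold, the seed storage gene CRA1 (2.35), the root regulator SHR (1.95) and VRN2 itself (1.4), whose sequence the transgene also holds. The 5 peaks of highest mean fold included those at AT1G32920 (chromosome 1, 11928882 to 11929947, fold 8.18, SD 3.26) and at LHCB4.1. Another lay at ERD15 and AT2G41440 (chromosome 2, 17269412 to 17270798, fold 6.81, SD 3.61). The others lay at no gene with coordinates (chromosome 4, 3054312 to 3054890, fold 5.89, SD 1.04, and chromosome 4, 5579058 to 5580857, fold 5.21, SD 2.0). The 3 lists held 2523, 2762 and 4586 peaks, of which 1402 merged peaks were in at least 2 lists and 494 in all 3, and 868 genes were bound. Replicates 1 and 2 shared 43% and 39.4% of their peaks with each other and 27.8% and 24.7% with replicate 3, and of the longer list of replicate 3, 15.6% and 15.1% were in the others. Without replicate 1 there were 646 reproducible peaks and without replicate 2 677. The folds are the authors' own, and an untagged control was not analysed here.

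H3K27me3 differed between vrn2-5 and Col-0 at many regions by small amounts. With the first library of each comparison read as vrn2-5, which the tables do not state, 1787 regions were reproducibly lower in vrn2-5 and 497 higher, so that 78.2% were lower. Each replicate comparison sets a single library of each genotype against the other, so its false discovery rate does not measure the spread between samples. How many regions would recur in the same direction by chance was not tested. If the libraries stand the other way round, 1787 were higher and 497 lower, and every direction in this and the following paragraphs turns with them. Genes with a lower region included 6 of 13 salicylate defence genes, FMO1 and PR1 among them (adjusted p = 0.0379 by Fisher's exact test), 5 of 11 abscisic acid and cold genes such as RAB18 and CBF3 (adjusted p = 0.0489), and 8 of 30 PIF and shade genes (adjusted p = 0.0863). The background was all 21713 nuclear genes with coordinates, of which 7027 were marked and 2568 had a lower region. Marked were 8 of the 13 salicylate defence, 5 of the 11 abscisic acid and cold and 14 of the 30 PIF and shade genes. These tests thus do not separate presence of the mark from its difference, and no list was tested among marked genes alone. At ST2A the log2 ratio of vrn2-5 to Col-0 averaged -0.32 (SD 0.116, n = 3) and at CKX5 -0.093 (SD 0.0515), while FUL, a flower and fruit regulator, stood at 0.096 (SD 0.0253) and PI at 0.114 (SD 0.0241). The developmental Polycomb targets ran the other way as a list, with a higher region at 11 of 24 genes (adjusted p = 2.06e-09, a test added after the data were seen) and a lower one at 3 (adjusted p = 0.92). As known Polycomb targets, 21 of 24 developmental genes were marked (adjusted p = 5.75e-07), as were 7 of 8 root tissue markers and 14 of 21 early auxin genes (adjusted p = 0.0121 for both).

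The tables held 4768, 6518 and 6357 regions with 4.37 to 7.62 M reads per library inside them. Lower and higher regions numbered 3048 and 517, 1756 and 1631, and 1538 and 734, with median log2 ratios of -0.163, -0.011 and -0.0358. With a fold of at least 2, 1 region was reproducibly lower and none higher. Without replicate 1 there were 1041 reproducible regions and without replicate 2 1226. Limma on the 3 log2 ratios called 608 of 3786 regions with 94.9% lower, and 470 with 76.8% lower after each table was centred on its median.

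**Figure D3:**
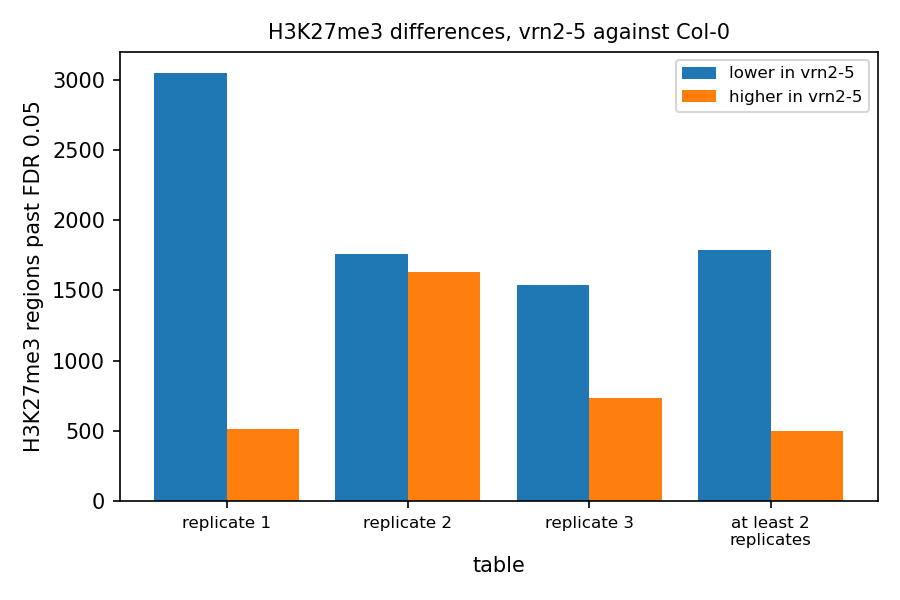
Number of H3K27me3 regions past a false discovery rate of 0.05 in each replicate table and in at least 2 tables, lower or higher in vrn2-5 than in Col-0 when the first library is read as vrn2-5. Lower regions outnumber higher ones in each table, by 1787 to 497 for the reproducible set and by 1756 to 1631 in replicate 2.

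VRN2-YFP peaks lay mostly inside H3K27me3 regions. Of 1402 reproducible peaks, 73.3% (1028) lay inside a region found in at least 2 tables, against 29.9% for shifted peaks (highest 34.7%; permutation p = 0.001, the smallest that 1000 shifts can give). Among 16351 genes tested for expression and with coordinates, 363 of 516 bound genes were marked (odds ratio 6.82, p = 1.53e-95 by Fisher's exact test) and 199 had a lower region (6.29, p = 1.8e-69). Without replicate 1 the first odds ratio was 4.07, and without replicate 2 the second was 3.92. Higher regions were at 28 bound genes (1.88, exact p = 0.00366), with 2.7 (p = 0.000643) for gene bodies and 2.14 (p = 8.09e-07) over all nuclear genes. This association was 1.05 (exact p = 0.717) when all 3 replicates were required, 1.27 (p = 0.515) without replicate 1 and 2.4 (p = 0.0236) without replicate 2. Of the peaks, 8.42% lay inside reproducibly higher regions, against 3.99% for shifted peaks (highest 5.78%, permutation p = 0.001). Inside reproducibly lower regions lay 30.8%, against 7.84%. Among marked genes, bound genes more often had a lower region (54.8% against 35.2%, odds ratio 2.24, exact p = 3.19e-13, but 1.41 and p = 0.0566 without replicate 2). They less often had a higher one (odds ratio 0.645, exact p = 0.0294), a call lost in most other settings. This odds ratio was 0.78 (exact p = 0.0887) over all nuclear genes, 0.697 (p = 0.193) for gene bodies and 0.404 (p = 0.239) with all 3 replicates. It was 0.526 (exact p = 0.373) without replicate 1, 0.891 (p = 1) without replicate 2 and 0.48 (p = 0.00354) without replicate 3. Averaged over replicates, the median log2 ratio at bound genes was below that at other marked genes by a difference of -0.0298 (SD 0.0364, n = 3), within its spread.

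The chromatin classes met few expression changes. None of the 2 higher and the 1 lower gene with coordinates called in vrn2-5 was bound (p = 1 for each by Fisher's exact test). Both higher genes had a region of higher H3K27me3 (exact p = 0.000922, or 1 of 2 and p = 0.024 without replicate 1): AT3G29633, with a mean log2 ratio of 1.02 (SD 0.622, n = 3), and QQS, which also had a lower region. Over regions that touch QQS or 1 kb upstream, the log2 ratio was 0.284 in replicate 1 and -0.327 in replicate 3, with no such region in replicate 2. Merged regions can reach beyond those of a single table, so the calls at QQS may rest on more than these. The lower gene, AT1G03220, had no region. Lower H3K27me3 met 1 of the 2 higher genes (exact p = 0.19) and none of the lower (p = 1). With the unadjusted p under 0.05 in place of the adjusted, chosen after the data were seen, 18 of 246 lower genes were bound (odds ratio 2.47, exact p = 0.00119; 0.00119 to 0.129 over 6 settings) and 11 of 219 higher genes (1.64, p = 0.117; 0.0941 to 0.443 over 6 settings). On the same criterion 26 of the 219 higher genes had lower H3K27me3 (1.21, exact p = 0.363), with p from 0.00423 to 0.431 and odds ratios from 1.21 to 2.2 over 6 settings. By camera no set of bound or marked genes passed in vrn2-5 against Col-0, where 234 of 516 bound genes were positive (adjusted p = 0.749) and 820 of 1637 genes with lower H3K27me3 (adjusted p = 0.986).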

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

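The comparisons of genotypes and their interaction were planned, while the tests of explanations and the other splits of the libraries were chosen after the results were seen.

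MRD1 (AT1G53480) stood out because the effect of vrn2-5 differed between the backgrounds, with an interaction of 6.178 on the log2 scale (SE 0.591). Neither edgeR on recovered reads nor limma at pseudocount 1 called this interaction. It averaged 219.5 normalized reads in Col-0 (SD 28.7), 0.178 in vrn2-5 (SD 0.307), 1.16 in libraries labelled prt6-1 (SD 1.01) and 6.40 in the double mutant (SD 6.57, n = 3 each), so there was little left to lose where prt6-1 was present. Chance cannot be excluded for the number of interactions: 40 of 100 splits of the 12 libraries gave as many genes as the 1 observed, and the highest of the others gave 13. No count was made with replicate 3 libraries kept on each side, so their shared structure may enter these splits.

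The genes changed in vrn2-5 against Col-0 form the first pattern: Col-0 differs from all 3 mutant genotypes in MRD1, QQS and AT3G29633, while AT1G03220 was low in vrn2-5 alone. A loss of VRN2 that acts alike with and without the prt6-1 label is argued against for AT1G03220 alone, which stood at its Col-0 level in prt6-1 and differed by -0.1054 (SE 0.185) in vrn2-5 prt6-1 against prt6-1, after -1.77 (SE 0.185) in vrn2-5, although its interaction did not pass over all genes (adjusted p = 0.325); the other 3 were already past 50% of their vrn2-5 change in prt6-1, so nothing decides for them. Col-0 libraries that stand apart for a technical reason are argued against too, since 3 of the 3 genes measured in rosettes, where no Col-0 library enters, differed there in the same direction by more than 2 SE. What stays open is a difference carried by the plant lines, such as a variant or an inherited silencing state fixed in some stocks, which may account for the 3 genes that differ in rosettes. It cannot be told apart from an effect of VRN2. Each genotype may come from a single line, and of the called genes only AT1G03220 had room to change in the prt6-1 background. PTR1, not called and chosen after its values were seen, ran like AT1G03220. It differed by -3.726 (SE 0.534) in vrn2-5 against Col-0 and by 0.6274 (SE 0.534) in vrn2-5 prt6-1 against prt6-1. In rosettes it differed by -4.135 (SE 0.612).

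Other splits of the 6 libraries compared are too few, at 10 for each comparison, for a share under 0.05. For vrn2-5 against Col-0, 4 splits gave at least the 4 genes observed and the highest other gave 15. For prt6-1 against Col-0, 1 split, the real one, gave 31 or more and the highest other 4. For vrn2-5 prt6-1 against prt6-1, all 10 gave at least 0 and the highest other 1. For vrn2-5 prt6-1 against vrn2-5, 1 split gave 35 or more and the highest other 4. For vrn2-5 prt6-1 against Col-0, 1 split gave 35 or more and the highest other 17. In the 3 comparisons with Col-0, the highest other split put both replicate 3 libraries on the same side, which points to a structure of the samples. For prt6-1 and vrn2-5 prt6-1 the same split set the shallow libraries against the deep ones, and for vrn2-5 the side without replicate 3 was all shallow, so these splits do not separate replicate 3 from depth. Among the 6 splits with 1 replicate 3 library on each side, the highest others were 11, 0 and 0 for vrn2-5, prt6-1 and vrn2-5 prt6-1 against Col-0, and 3 splits of the first gave at least 4 genes.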

How the results depend on the processing

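Several settings were added after the data were seen: edgeR on recovered reads, the deep or shallow libraries alone, a depth term, a replicate 3 term, pseudocount 1, removal of the length trend, other H3K27me3 folds, limma on those folds, and the unadjusted p in overlaps. Where a count moved by more than 1.5 times the cause was not tested, unless fewer libraries or a stricter rule brought it about. With DESeq2 the counts were 11 for vrn2-5 against Col-0, 55 for prt6-1 against Col-0, 63 for vrn2-5 prt6-1 against vrn2-5, 68 for vrn2-5 prt6-1 against Col-0, 6 for the interaction and 7 in rosettes. With only the 6 libraries compared they were 1 for vrn2-5 against Col-0 and 23 for the double mutant against Col-0. The 6 deep libraries alone gave 0, 2, 7, 6 and 0 genes for vrn2-5, prt6-1, vrn2-5 prt6-1 against vrn2-5, vrn2-5 prt6-1 against Col-0 and the interaction, and the 6 shallow ones 0 for each, with fewer libraries per test. The interaction also had 0 genes with edgeR on recovered reads, under RLE or TMM scaling. At pseudocount 1 it had 1 gene, with 0 shared with the gene called at 5. Leaving out each library gave 1 to 23 genes for vrn2-5 against Col-0, 21 to 51 for prt6-1 against Col-0, 23 to 53 for vrn2-5 prt6-1 against Col-0, 0 to 5 for the interaction and 2 to 11464 in rosettes. The correlation of the rosette and seedling vrn2-5 effects lay between -0.00107 and 0.0287 on leaving out a rosette library.

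The replicate numbers do not pair the libraries throughout, but replicate 3 is a set shared across genotypes: its 6 pairs of libraries deviated with correlations from 0.288 to 0.56, against -0.215 to 0.26 for replicate 1 and -0.216 to 0.219 for replicate 2, and 5 of 12 libraries correlated best with their own number. With replicate 3 as a term, counts were 4 for vrn2-5 and 37 for prt6-1 against Col-0, 0 for vrn2-5 prt6-1 against prt6-1, 54 against vrn2-5 and 57 against Col-0, and 1 for the interaction, and seedling camera calls went from 15 to 16 with all 15 kept (3 and 3 with an estimated correlation). With the replicate block, seedling counts were 4, 30, 0, 38, 44 and 1, within 1.5 times of those without it, and edgeR on recovered reads with the block gave 0 for the interaction. Rosette counts with the block were 3 genes, and 2 after removal of the length trend, against 0 without it. Camera made 17 calls as set, 3 with an estimated correlation (all the hypoxia list), 19 with the block and 18 with RLE, and all 17 recurred under the last 2.

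There were 494 peaks in all 3 lists, against 1402 in at least 2, and 646 to 1062 on leaving out a replicate. H3K27me3 regions numbered 782 in all 3 tables, 1033 at a false discovery rate of 0.001, 1 at a fold of 2, 58 at a fold of 1.5, 301 at the smaller fold after centring, 608 and 470 by limma as deposited and centred, and 1041 to 1583 on leaving out a replicate. The odds ratio of bound genes and higher regions was 1.05 with all 3 replicates (1.18 over all nuclear genes) and 1.27 to 2.4 on leaving out a replicate (1.31 to 2.65). Among marked genes it was 0.697 for gene bodies, 0.404 with all 3 replicates and 0.48 to 0.891 on leaving out a replicate (0.521 to 1 over all nuclear genes). For lower regions among marked genes it was 1.41 to 3.15 (1.21 to 2.55). With the unadjusted p, Fisher's p was 0.117 and 0.00119 for bound genes higher and lower in vrn2-5, 0.592 for lower mark with lower expression and 0.842 for higher mark with higher expression. For lower mark with higher expression, Fisher's p with the adjusted p of expression was 0.19 as set, 1 with all 3 replicates and 0.0778 to 1 on leaving out a replicate, and with the unadjusted p 0.363 (0.00423 to 0.431 over 6 settings).

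Over 51 pairs of named gene and comparison, 703 settings kept direction and side of the threshold, while 36 lost a call and 13 gained one. In 10 settings the sign of a gene without a call turned. PRT6 in vrn2-5 prt6-1 against prt6-1 was -0.06299 under RLE, -0.05811 with DESeq2 and -0.07319 with edgeR on recovered reads, and -0.3666 to 0.3487 on leaving out a library. On leaving out a library PRT6 in vrn2-5 was -1.858 to 0.1298, VRN2 in prt6-1 -0.2094 to 0.02542, LNG2 in prt6-1 -0.09562 to 1.584, and PIF4 in vrn2-5 prt6-1 against prt6-1 -0.1162 to 0.3059. Another pseudocount for rosettes was not run, since those columns hold counts. Depth limits the shallow libraries most, where 1 read equals 3.35 to 5 normalized reads.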

Other observations

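The tests of sequencing depth, of peaks that meet by chance and of expression at bound genes without the mark were chosen after the result was seen, while those of gene length, genotype and high transcription were set before.

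The plastid-encoded genes psbA and rbcL and the nuclear genes NIT2 and SAG13, chosen after their values were seen, read far higher in vrn2-5 pif4-2 rosette replicate 1 than in the other 3 rosette libraries. The photosystem gene psbA read 302 CPM in that library against 17.3, 24.3 and 10.1 in the other libraries, and rbcL, the large subunit of Rubisco, 169 against 12.2, 15 and 9.35. The nitrilase gene NIT2 read 95 against 0.536, 0.612 and 0, and the senescence-associated SAG13 79.8 against 0.67, 0.653 and 0.76. In seedlings AT5G05200 averaged 783.7 normalized reads in Col-0 (SD 48.6), 753.5 in vrn2-5 (SD 52.2), 128.3 in prt6-1 (SD 5.04) and 128.3 in the double mutant (SD 10.1), and it lies on chromosome 5 at 1544007 to 1547207, on the same arm as PRT6 at 473868 to 482942.

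The second pattern is that vrn2-5 pif4-2 rosette replicate 2 stands apart from the other 3 rosette libraries. Lower sequencing depth is argued against, since it held the most reads of the 4, at 26.3 M. It also detected the fewest genes, 17312 against 19394, 21081 and 21189, which the number of reads leaves unexplained. An effect of the genotype that dominates both replicates is argued against as well. The changes of replicates 1 and 2 over their own pif4-2 libraries had a rank correlation of -0.0145 across genes. Replicate 1 read far higher in psbA, rbcL, NIT2 and SAG13, so this correlation cannot exclude a smaller effect of the genotype. A bias against long genes in vrn2-5 pif4-2 replicate 2 remains a candidate explanation. Its log2 ratio and gene length had a rank correlation of -0.406. Such a bias may come from RNA quality or library preparation, neither of which was tested. How much of the difference between replicates length accounts for was not tested.

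The third pattern is the set of VRN2-YFP peaks outside every H3K27me3 region, 313 of 1402, with that over LHCB4.1 among them. Unrelated peaks that meet by chance are argued against, since 317 shared peaks outside regions compare with at most 40 in 200 shifts of the lists along the sequence outside regions (mean 24); of merged intervals, 12.6% of 2481 outside and 20.2% of 5395 inside were in at least 2 lists, and of those reproducible peaks 47% of 313 outside and 31.9% of 1089 inside were in all 3 (median fold 2.1 for both). High transcription, where open chromatin can raise any immunoprecipitation, stays open. Bound genes without a region had a median expression percentile of 69.1 in Col-0, against 44.5 for bound genes with one. Of the former 24.8% were in the top 5% of genes, but their median fell short of the 75 set beforehand. Genes neither bound nor with a region had a median of 54.5, with 5.91% in the top 5%. An effect of VRN2 on these genes stays open too, with camera p = 0.0506 downward in vrn2-5 against Col-0 (45 of 121 positive) and p = 0.00467 downward in vrn2-5 prt6-1 against prt6-1 (adjusted p = 0.0327, and adjusted p = 0.343 with an estimated correlation). Without an untagged control these cannot be told apart, and 8 of the 20 highest genes in Col-0 were bound.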
